A study of Mus musculus with 8 samples.

How the data were processed

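Liver RNA of mice lacking Stat5a and Stat5b in hepatocytes and of floxed controls was measured by stranded RNA sequencing after removal of ribosomal RNA. Stat5a and Stat5b are neighbouring genes that encode transcription factors through which growth hormone acts on liver. The knockout was made by crossing an albumin-Cre line, of FVB/N background per the labels, to mice with floxed alleles on a mixed C57BL/6 and 129J background, so the deletion falls mainly in hepatocytes while other liver cells keep both genes. Animals were 8 to 12 weeks old. The 4 groups were control male, knockout male, control female and knockout female, each with 2 libraries, and every library was made from a pool of livers whose number of animals the labels do not give. The p-values can therefore rest at most on the spread between pools, not between animals. A small p-value of the authors' edgeR test does not show that the 2 pools of a group lay close together for that gene, as Tgtp1 below shows. The titles also carry a library code whose meaning is not stated. Both knockout female libraries carry G137, both control female libraries G138 and both control male libraries G140, while 1 knockout male library carries G138 and the other G140.

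TopHat2, featureCounts and edgeR are named in the submitters' processing notes, with mm9 as the genome build; versions, annotation and filters are not given in the sources used here. The deposited table lists 24197 genes with their coordinates. Expression is given as the mean FPKM of each group, computed by the authors per the file headers. For each of 4 comparisons the authors give a normalized expression ratio and a p-value from edgeR, per the file headers. The authors' adjusted p-value was checked to equal the Benjamini-Hochberg adjustment of their p-value over all listed genes, within rounding. A gene was counted as called where the authors' adjusted p-value was under 0.05. FPKM divides reads by gene length and by a library total, so a few very abundant transcripts take a share of that total from all others, and the mean hides how far apart the libraries of a group lie.

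The values of single libraries are not listed, and were recovered from the mean FPKM. Each mean is the average of 2 ratios of whole reads to a library total, divided by the gene length, and the table keeps enough decimals to solve for both read numbers. The library totals were read from genes with 1 read, and for each gene annotated exon lengths were tried first and then increasing lengths, until a length gave whole reads in all 4 groups within a tolerance of 1e-08 reads on top of the table's rounding. Of the 24197 genes, 6193 were listed at 0 in all 4 groups, and all other 18004 were solved, 3257 with an exon length of the GENCODE M21 annotation and 14747 with a searched length. The largest difference between the FPKM recomputed from recovered reads and the deposited FPKM was 2.2e-11. On simulated reads, all 8 read numbers came out right for 246 of 246 genes with at least 50 reads. For genes with fewer reads, numbers that share a common divisor could come out too small, which leaves the FPKM of each library unaffected. The recovery tells the 2 libraries of a group apart only by their totals, so they are called the deeper and the shallower library, and no recovered library was assigned to a pool number or library code. Means and SDs in FPKM come from the recovered libraries with n = 2.

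Before the data were examined, edgeR's quasi-likelihood test was planned for a table of counts, and limma on log2(value + 1) for a table without counts. The table holds neither counts nor single libraries, and the calls reported first are those of the authors' deposited table. The planned edgeR test was not run on the recovered reads. Beside them stand the calls of the planned fallback, limma on log2(FPKM + 1) of the recovered libraries, with trend = TRUE in its moderation step, and those of limma voom on the recovered reads, an added alternative. The decision to lead with the authors' calls was made after the counts of the refits were seen. The refits use all 8 libraries and 4 residual degrees of freedom, and call far fewer genes. For voom, genes needed at least 10 reads in at least 2 libraries, which left 12980, and library sizes were scaled by the median of ratios. The genotype by sex interaction, for which no test by the authors was used, was tested with limma on log2(FPKM + 1), a scale that understates changes of low genes. The voom fit was tested on simulated counts with each gene's mean over the 4 groups and the real library sizes. With 200 genes changed in the male knockout comparison, it recovered 39 of 100 changed by a fold of 2 and 72 of 100 changed by a fold of 4, among 12788 genes tested, and 6 of its 117 calls were unchanged genes. A first version of the simulation gave all genes of one expression level the same dispersion and made far more calls than the real data. It was replaced by one with scatter between genes, drawn with 3 degrees of freedom, a number set after comparing the spreads. The new version still made more calls than the real data where the sex difference of called genes was kept. Over 20 runs voom called a mean of 136.65 male-biased and 142.95 female-biased genes, against 63 and 36 in the data. The recovery above may therefore be too high for the real data.

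Fixed before the data were examined were 28 gene lists. They covered male-biased and female-biased liver genes, sex-chromosome genes, growth hormone response genes, growth-arrest and oxidative stress targets of STAT5, the interferon response, the acute phase response, lipogenesis and lipid storage, PPARalpha targets, cholesterol synthesis, bile acid synthesis and transport, gluconeogenesis and fasting, the cell cycle, fetal and tumour-associated liver genes, the circadian clock, immediate early and stress genes, perivenous and periportal zone genes, and markers of hepatocytes, Kupffer cells and macrophages, lymphocytes, neutrophils, endothelial cells, stellate cells, bile duct, red blood cells, pancreas and adipose tissue. Some genes stand in more than 1 list. Lists with at least 3 tested members were tested with camera on the voom values at a preset inter-gene correlation of 0.01, with adjustment over the 26 lists tested within a comparison. No list passed with a correlation estimated from the data in any of the 5 comparisons. Between control males and females, the sex-chromosome and male-biased lists each gave an adjusted p of 0.0578 in camera with that setting. Failing to pass it therefore does not show that a list is unchanged. The fry test of whether a list moves, on balance, one way was a further alternative. Within a list, calls are counted over all genes and adjusted over the list alone, both from the authors' p-values, and by voom.

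The rule for named genes took Stat5a, Stat5b and sex-chromosome genes first. It then took the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 1 and no overlap between the groups' libraries, 5 each way for the sex difference between knockouts and for the interaction, and up to 4 members of each list with the lowest adjusted p-values. Some genes that the rule takes are not reported here. Genes outside the rule are said to be chosen after their values were seen. Coordinates are those of the deposited table. Planned and added alternatives covered pseudocounts of 1 and 0.1, filters, scaling, the libraries in the fit, a fold threshold of 2 and leaving out each library. Reads of closely related genes, such as the Mup, Sult2a, Saa and Cyp families, may be divided unevenly between copies, and 15 pairs of genes had the same reads in every library. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.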

Results

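The data are liver transcriptomes of mice without Stat5a and Stat5b in hepatocytes and of floxed controls, in both sexes, with 2 libraries from pooled livers in each of the 4 groups. The library totals behind the FPKM ran from 6192515 to 34651386, and reads in genes from 2288033 to 11361272. The shallower control male library was the smallest, with reads in 14072 genes against 16266 in the deeper control female library. Albumin was the most abundant transcript in every library, and the 10 most abundant genes took 16.2% to 20.9% of the reads.

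Transcripts of both targeted genes fell in the knockout livers of both sexes. Stat5b (chromosome 11, 100642044 to 100711899 on mm9, NM_011489) averaged 2.68 ± 1.04 FPKM in control males and 0.859 ± 0.247 in knockout males (SD, n = 2). In females it averaged 3.39 ± 0.698 in controls and 1.44 ± 0.468 in knockouts (SD, n = 2). The authors' deposited table gives Stat5b as 2.97-fold lower in knockout males with an adjusted p of 3.1e-06 and 2.58-fold lower in knockout females with an adjusted p of 3.5e-06. Stat5a (chromosome 11, 100720664 to 100746483, NM_011488) averaged 0.881 ± 0.398 FPKM in control and 0.178 ± 0.0684 in knockout males, and 0.862 ± 0.0825 in control and 0.31 ± 0.268 in knockout females (SD, n = 2). The authors' deposited table gives Stat5a as 4.49-fold lower in knockout males, adjusted p 1.4e-05, and 2.99-fold lower in knockout females, adjusted p 0.024. The lowest control library lay above the highest knockout library for both genes and both sexes, in the plot of FPKM per library. With limma voom, the adjusted p of Stat5b was 0.049 in males and 0.084 in females, and that of Stat5a 0.15 and 0.24. Reads from the loci remained in every knockout library, from 11 to 59 for Stat5a, and values for whole genes do not separate deleted exons from the rest of the transcript or hepatocytes from other liver cells.

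**Figure D1:**
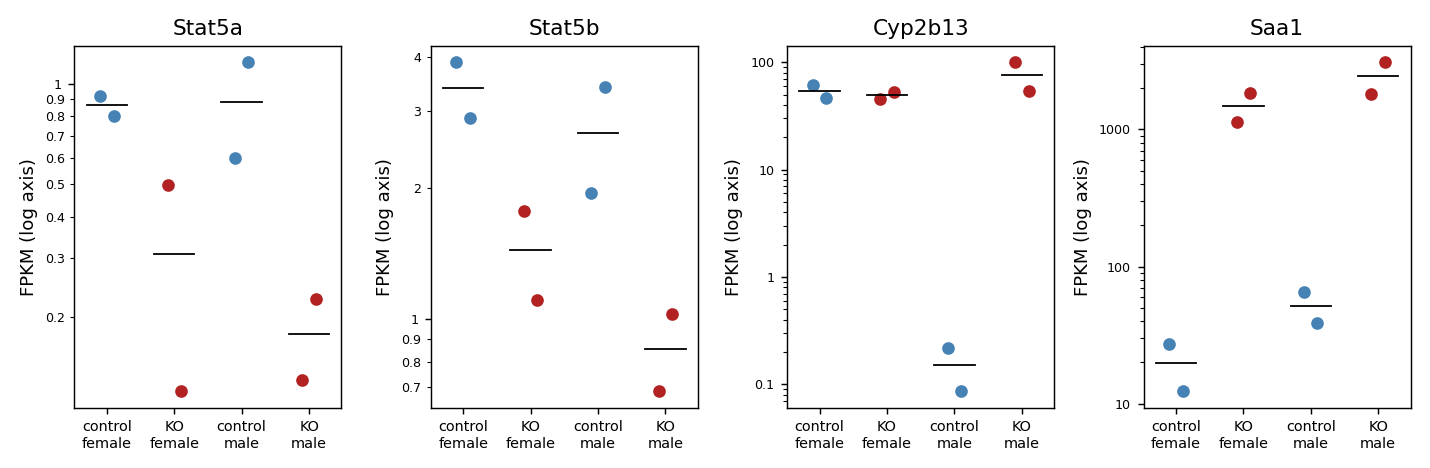
FPKM per recovered library on a log axis for Stat5a, Stat5b, Cyp2b13 and Saa1, with the 4 groups along the horizontal axis; each point is 1 library and each black line the mean of the 2 libraries. Stat5a and Stat5b are lower in knockouts of both sexes, Cyp2b13 averages 0.153 FPKM in control males against 76.5 in knockout males, and Saa1 averages 51.8 and 19.8 in control males and females against 2450 and 1480 in the knockouts.

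Sex-chromosome genes matched the labelled sex in every group. Xist, the RNA of the inactive X chromosome, averaged 43.8 ± 2.46 FPKM in control and 46.6 ± 1.88 in knockout females, and 0.143 ± 0.142 in control and 0.124 ± 0.0552 in knockout males (SD, n = 2). Y-linked Ddx3y averaged 12.1 ± 0.205 FPKM in control and 9.51 ± 1.25 in knockout males, against 0.0205 ± 0.0115 and 0.0254 ± 0.0159 in females (SD, n = 2).

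The first comparison asked what loss of Stat5a and Stat5b does in male liver. Most listed genes known to be higher in male liver fell and many known to be higher in female liver rose. The authors' deposited table calls 528 genes at an adjusted p under 0.05, 336 higher and 192 lower, and 454 of them changed by at least 2-fold. Among 34 male-biased liver genes, 29 fell and 0 rose in the authors' edgeR test (0 higher and 33 lower adjusted over the list alone, 15 lower by voom). Their median log2 ratio was -2.10. Camera gave an adjusted p of 1.26e-30, and the call was lost with an adjusted p = 0.135 with an estimated correlation. Examples per the authors' deposited table are Hsd3b5, a 3-ketosteroid reductase, 11.3-fold lower with an adjusted p of 1.5e-18, Cyp7b1, an oxysterol hydroxylase, 7.2-fold lower with 9.2e-13, and the urinary protein genes Mup7 and Mup1, 6.3-fold and 4.5-fold lower with 1.3e-16 and 3.6e-17. Hsd3b5 averaged 67 ± 31.8 FPKM in control and 5.76 ± 2.95 in knockout males (SD, n = 2). Its voom log2 change was -3.56 with a standard error of 0.39 and an adjusted p of 0.0055. Of 46 female-biased liver genes, 28 rose and 1, Cyp2c69, fell (31 and 3 adjusted over the list alone, 5 and 0 by voom). Their median log2 ratio was 1.80. Camera gave 2.26e-13, lost with an adjusted p = 0.377 with an estimated correlation.

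Cyp2b13, a cytochrome P450 of female liver, led the named rises. It averaged 0.153 ± 0.0943 FPKM in control males and 76.5 ± 32.7 in knockout males, beside 54.4 ± 10.5 in control females (SD, n = 2). The authors' deposited table gives a 391-fold rise with an adjusted p of 4.5e-66, and 141-fold and 140-fold rises of the sulfotransferase genes Sult2a2 and Sult2a1. Sult2a6 was at 0 reads in both control male libraries and averaged 1.9 ± 1.05 FPKM in knockout males (SD, n = 2). The sulfotransferase Sult1e1, which inactivates oestrogens, was 81.2-fold higher in the authors' deposited table with an adjusted p of 5.1e-48. Further large rises were those of the interferon-inducible GTPases Tgtp1 (277-fold) and Tgtp2 (112-fold), of Igdcc4 (210-fold) and of Apol10b (114-fold) in the authors' deposited table. The Tgtp1 level rested on wide spread, 5.91 ± 6.07 FPKM in knockout against 0.0122 ± 0.0173 in control males (SD, n = 2). Its adjusted p was 1.3e-13 in the authors' edgeR test but 0.53 by voom, while the voom adjusted p of Igdcc4 was 0.0044. Voom called Cyp2b13 as well, but not the rises of Sult2a6, Sult2a2, Sult2a1, Tgtp2 and Apol10b. Of these uncalled rises, limma on log2(FPKM + 1) called that of Sult2a2. Among genes with an average log2 CPM of at least 1 and no overlap between the libraries of the groups, the largest falls in the authors' deposited table were Serpina1e (18-fold), Hsd3b5, the fatty acid elongase gene Elovl3 (11.2-fold), Ugt2b38 (10.6-fold), Cyp7b1, Csad (7.13-fold), Serpina4-ps1 (6.99-fold) and Acsm2 (6.74-fold). Control males themselves differed widely for Serpina1e, 335 ± 416 FPKM, and Elovl3, 40 ± 48.7 FPKM (SD, n = 2). Voom did not call the falls of Serpina1e, Elovl3, Csad and Serpina4-ps1. Limma on log2(FPKM + 1) called none of these largest falls.

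Of 20 growth hormone response genes, 7 fell and 1 rose (8 and 3 adjusted over the list alone, 4 lower and 0 higher by voom). Camera gave an adjusted p of 7.96e-05, lost with an adjusted p = 0.377 with an estimated correlation, and fry gave 0.109. Igf1, the growth factor that liver secretes under growth hormone, averaged 49.2 ± 2.7 FPKM in control and 14.8 ± 4.4 in knockout males (SD, n = 2). The authors' deposited table gives Igf1 as 3.29-fold lower with an adjusted p of 4.4e-10, the feedback inhibitor gene Socs2 as 4.43-fold lower with 4.3e-10, the receptor gene Egfr as 3.3-fold lower with 8.8e-09 and Igfals, which encodes a binding partner of circulating IGF1, as 2.97-fold lower with 4.7e-06. Ccnd1 was the 1 higher member, 2.2-fold in the authors' deposited table. Of 7 growth-arrest and oxidative stress targets of STAT5, only Cdkn1a, the gene of the cell cycle inhibitor p21, was called, 17.1-fold higher in the authors' deposited table with an adjusted p of 1.4e-08. Adjusted over the list alone 1 was higher and 1, Nox4, lower, limma voom called 0 with 3 of the 7 at an unadjusted p under 0.05 in the authors' edgeR test, and camera gave 0.397 and fry 0.115 for the list.

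Many acute phase and interferon genes rose. Of 28 acute phase genes, 19 rose and 0 fell (23 and 0 adjusted over the list alone, 13 and 0 by voom). Camera gave 2.87e-23, lost with an adjusted p = 0.242 with an estimated correlation, and fry gave 0.0247. The authors' deposited table gives 99.6-fold and 46-fold rises of the serum amyloid genes Saa2 and Saa1, a 78.2-fold rise of Orm2, a 58-fold rise of Lcn2 and a 4-fold rise of haptoglobin (Hp), with an adjusted p of 2.4e-14 for the last. Lcn2 averaged 3.7 ± 0.394 FPKM in control and 210 ± 13 in knockout males (SD, n = 2), with a voom adjusted p of 0.0055. Of 46 interferon response genes, 26 rose and 0 fell (38 and 0 adjusted over the list alone); limma voom called 0 of them, and camera gave 5.81e-15, lost with an adjusted p = 0.454 with an estimated correlation, while fry gave 0.267. Examples per the authors' deposited table are Usp18, 7.22-fold higher with an adjusted p of 4.7e-10, Igtp, 6.16-fold with 6.3e-08 and Gbp3, 21-fold with 3e-08.

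Few genes of the metabolic lists were called. Lipogenesis and lipid storage genes had 4 of 32 higher (4 adjusted over the list alone, 1 by voom; camera 0.409), among them the fatty acid transporter gene Cd36, 9.74-fold higher in the authors' deposited table with an adjusted p of 5e-26. Cholesterol synthesis had 3 of 23 lower and 0 higher (7 and 1 adjusted over the list alone, 1 and 0 by voom), namely Tm7sf2, Idi1 and Nsdhl, 1.68-fold to 1.89-fold lower in the authors' deposited table; camera gave 6.33e-04, lost with an adjusted p = 0.539 with an estimated correlation. Bile acid synthesis and transport had 2 of 20 lower, Cyp7b1 and the transporter gene Slco1a1, and 1 higher, Abcc4 (3 and 2 adjusted over the list alone; camera 0.397). In the gluconeogenesis and fasting list 1 of 18 rose, Igfbp1, an IGF binding protein gene induced by fasting, 11-fold in the authors' deposited table with an adjusted p of 4.4e-17 (camera 0.173). Periportal zone genes had 3 of 14 lower and 1 higher (5 and 1 adjusted over the list alone; camera 4.69e-04, adjusted p = 0.49 with an estimated correlation), with Etnppl 4.58-fold lower and Hsd17b13 2.2-fold higher in the authors' deposited table. Perivenous zone genes had 2 of 16 higher, Rhbg and Cyp2c37 (camera 0.521). Fetal and tumour-associated genes had 3 of 14 higher, Spink3, H19 and Golm1 (camera 0.0632), Spink3 being at 0 reads in both control male libraries and at 4.54 ± 1.2 FPKM in knockout males (SD, n = 2). In the cell cycle list 1 of 28 rose, Ccnd1 (camera 0.0326, adjusted p = 0.609 with an estimated correlation). In the circadian list 1 of 18 fell, Bhlhe41 (camera 0.757), and in the immediate early list 2 of 16 rose, Btg2 and Hspa1b (camera 0.0249, adjusted p = 0.539 with an estimated correlation).

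Markers of cell types were also compared in males. Kupffer cell and macrophage markers had 3 of 18 higher, Mpeg1, Lyz2 and C1qa (10 adjusted over the list alone, 2 by voom), with a median log2 ratio of 0.533 beside the 1.47 of the interferon list; camera gave 3.13e-09, lost with an adjusted p = 0.377 with an estimated correlation. Hepatocyte markers had 1 of 22 lower, Serpina1a, 1.88-fold in the authors' deposited table (2 lower adjusted over the list alone; camera 0.0028, adjusted p = 0.49 with an estimated correlation). Of the bile duct markers only Spp1, which encodes osteopontin, was called, 9.06-fold higher in the authors' deposited table with an adjusted p of 3.8e-15 (camera 0.0549). Of the pancreas markers Cela1 was called, 2.75-fold lower in the authors' deposited table. Adjusted over the list alone, 4 others were higher, Prss2, Pnlip, Cel and Ctrb1. The 11 pancreas genes apart from Cela1 summed to 24 and 79 reads in the deeper and shallower knockout male libraries, against 6 and 0 in control males, 9 and 2 in control females and 3 and 5 in knockout females. The 8 lists with no call in the authors' edgeR test were the PPARalpha, sex-chromosome, lymphocyte, neutrophil, endothelial, stellate, red blood cell and adipose lists, with 13 of their 120 members at an unadjusted p under 0.05 and 0 called by voom. Camera gave adjusted p-values of 0.223 for PPARalpha targets, 0.236 for sex-chromosome genes, 0.095 for lymphocyte, 0.452 for endothelial, 0.0632 for stellate, 0.397 for red blood cell and 0.757 for adipose markers. The neutrophil and pancreas lists had 2 and 1 members past the read filter, too few for a camera test.

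For this male comparison limma on log2(FPKM + 1), the planned fallback, called 55 genes (46 higher, 9 lower), and limma voom 197 (100 higher, 97 lower), 183 of them among the authors' 528. Leaving out 1 library took the voom count to 53 without the deeper control male, 67 without the shallower control male, 90 without the deeper knockout male, 124 without the deeper and 122 without the shallower control female library.

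The same comparison in females gave 374 genes in the authors' deposited table, 251 higher and 123 lower, of which 250 changed by at least 2-fold. Many acute phase and interferon genes rose in females too. Of 28 acute phase genes 16 rose and 1, Apcs, fell (18 and 2 adjusted over the list alone, 8 and 0 by voom). Camera gave 2.53e-18, lost with an adjusted p = 0.343 with an estimated correlation, and fry gave 0.0673. Saa1 averaged 19.8 ± 10.7 FPKM in control and 1480 ± 504 in knockout females (SD, n = 2), and its voom log2 change was 6.06 with a standard error of 0.43 and an adjusted p of 0.0032. The authors' deposited table gives 84.5-fold and 67.7-fold rises of Saa2 and Saa1, 19.9-fold of Orm2 and 3.86-fold of Hp, with an adjusted p of 7.6e-53 for Saa1. Of 46 interferon response genes 26 rose and 0 fell (36 and 0 adjusted over the list alone); limma voom called 0, and camera gave 2.53e-18, lost with an adjusted p = 0.536 with an estimated correlation, while fry gave 0.384. Igtp, Tap1 and Psmb9 were among the members with the lowest adjusted p-values there, with rises of 5.84-fold, 3.84-fold and 3.25-fold in the authors' deposited table.

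Sulfotransferase genes stood among the largest rises in females, and serpin genes among the largest falls. Within the same limits on expression and overlap, the largest rises in the authors' deposited table were Apol10b (294-fold), Saa2, Sult2a7 (82-fold), Saa1, Chil1 (44.8-fold), Sult2a3 (34.1-fold), Gm4841 (33.9-fold) and Gm6614 (33.4-fold). Sult2a7 averaged 0.208 ± 0.0207 FPKM in control and 18.5 ± 1.55 in knockout females (SD, n = 2). Apol10b averaged 0.0145 ± 0.0206 and 7.05 ± 6.67 FPKM (SD, n = 2), and its voom adjusted p was 0.55, against 0.0053 for Sult2a7. Within these limits the largest falls in the authors' deposited table were Serpina4-ps1 (17.3-fold), Serpina12 (7.29-fold), the clock repressor gene Bhlhe41 (6.47-fold), Ankrd55 (5.77-fold), Smad9 (5.2-fold), Serpina3h (4.75-fold), Fam25c (4.44-fold) and the fatty acid binding protein gene Fabp5 (3.98-fold). For Serpina4-ps1 the control females spread over 93 ± 70.6 FPKM against 5.98 ± 5.57 in knockouts (SD, n = 2). None of the falls named here passed the threshold in limma on log2(FPKM + 1) or in voom. Among the rises, Chil1 and Gm6614 also failed to pass in either refit.

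Sex-biased genes moved both ways in females. Of 34 male-biased genes 5 rose (Cyp2d9, Cyp4a12a, Mup20, Nox4 and Bcl6) and 9 fell (8 and 13 adjusted over the list alone, 2 and 0 by voom); camera gave 0.0113 for a fall, lost with an adjusted p = 0.536 with an estimated correlation. The steroid hydroxylase gene Cyp2d9 rose 4.78-fold with an adjusted p of 2.2e-13 and the repressor gene Bcl6 3.97-fold with 3.4e-11, while Cyp7b1 fell 2.85-fold with 4.1e-11, all in the authors' deposited table. Of 46 female-biased genes 11 rose and 9 fell (13 and 12 adjusted over the list alone, 4 and 3 by voom; camera 0.681). Growth hormone response genes had 7 of 20 lower and 1, Bcl6, higher (10 and 3 adjusted over the list alone; limma voom called 0); camera gave 6.81e-04, lost with an adjusted p = 0.53 with an estimated correlation. Igf1 averaged 67 ± 14.4 FPKM in control and 30.4 ± 9 in knockout females (SD, n = 2), and the authors' deposited table gives it as 2.44-fold lower with an adjusted p of 3.7e-05. Growth-arrest and oxidative stress targets had 2 of 7 higher, Cdkn1a and the NADPH oxidase gene Nox4 (3 adjusted over the list alone, 1 by voom), 4.39-fold and 3.42-fold in the authors' deposited table; camera gave 1.82e-03, lost with an adjusted p = 0.343 with an estimated correlation, and fry gave 0.00367.

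PPARalpha targets had 5 of 30 higher and 0 lower in females (11 and 0 adjusted over the list alone; limma voom called 0); camera gave 8.01e-08, lost with an adjusted p = 0.536 with an estimated correlation. The authors' deposited table gives Pdk4 as 3.3-fold, Cyp4a31 as 3.06-fold, Cyp4a14 as 3.79-fold and Vnn1 as 4.69-fold higher. Lipogenesis had 4 of 32 higher, among them Cd36, G0s2, Fitm1 and Pparg (9 higher and 2 lower adjusted over the list alone; camera 0.0704). Gluconeogenesis and fasting genes had 2 of 18 higher, among them Igfbp1, 6.61-fold in the authors' deposited table with an adjusted p of 2.7e-24 (camera 0.0909). Periportal zone genes had 3 of 14 lower, Etnppl, Sult5a1 and Cyp2f2 (4 adjusted over the list alone; camera 0.00376, adjusted p = 0.536 with an estimated correlation). Perivenous genes had 1 of 16 higher, Slc1a4 (camera 0.601), bile acid genes 2 of 20 lower, Cyp7b1 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (camera 0.681), and fetal genes 2 of 14 higher, H19 and Spink3 (camera 0.188). The immediate early list had 3 of 16 higher, with Fos among them (camera 0.0222, adjusted p = 0.536 with an estimated correlation), with Hspa1a 5.93-fold and Hspa1b 3.73-fold higher in the authors' deposited table. The circadian list had 1 of 18 higher, Nfil3, and 1 lower, Bhlhe41 (camera 0.792).

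Among markers of cell types in females, Mpeg1, a perforin-like gene of macrophages, was the 1 Kupffer cell and macrophage marker of 18 that rose, 4.12-fold in the authors' deposited table, and the list's median log2 ratio was 0.15 (camera 0.0909). The 12 lists without a call in the authors' edgeR test were those for cholesterol, cell cycle, sex chromosomes, hepatocytes, lymphocytes, neutrophils, endothelium, stellate cells, bile duct, red blood cells, pancreas and adipose tissue. Together they had 20 of 186 members at an unadjusted p under 0.05, and voom called 0. By camera the stellate list was lower with 0.0113 and the red blood cell list lower with 0.0132, each lost with an adjusted p = 0.536 with an estimated correlation, and the others gave 0.576 for cholesterol, 0.947 for the cell cycle, 0.576 for sex chromosomes, 0.0704 for hepatocytes, 0.272 for lymphocytes, 0.0555 for endothelium, 0.934 for bile duct and 0.601 for adipose tissue.

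For this female comparison limma on log2(FPKM + 1) called 6 genes, all higher, and limma voom 46 (38 higher, 8 lower), all 46 among the authors' 374. The voom count went to 8 without the deeper and 13 without the shallower control female library, to 19 without the shallower knockout female library and to 30 without the shallower control male library. The knockout female libraries share their code with no other group, so code and group cannot be told apart here.

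**Figure D2:**
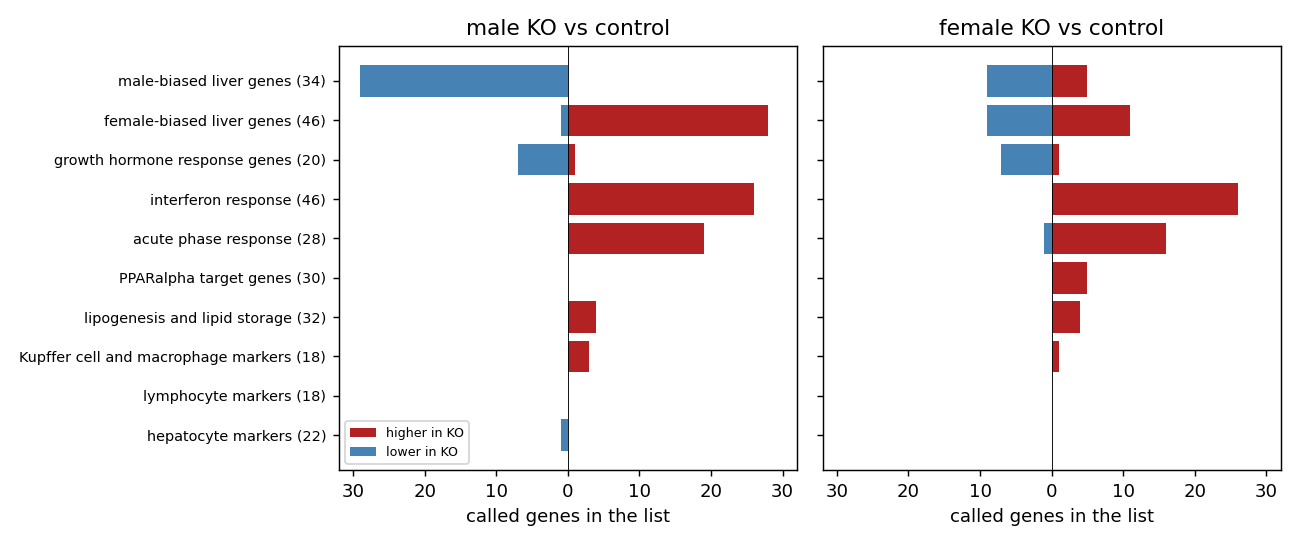
Called genes per list in the authors' edgeR test, for the male and the female knockout against controls of the same sex, with the number higher and lower on the horizontal axis. In males 29 of the male-biased list fell and 28 of the female-biased list rose, with 0 and 1 the other way, while in females 9 of the male-biased list fell and 5 rose, and 11 of the female-biased list rose and 9 fell; interferon genes had 26 higher in each sex.

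The knockout effects of the 2 sexes were compared across genes; these comparisons share no library. Of the 336 and 251 genes called higher in males and females, 141 were shared, against 4.68 for independent lists, and of the 192 and 123 called lower 58 were shared, against 1.31. Opposite calls were rarer, with 5 genes higher in males and lower in females (among them A1bg, Cyp2a4, Serpina3h and Slc22a26) and 2 the other way (Gm6614 and Mup20). Across 11386 genes with an average log2 CPM of at least 1, the log2 ratios had a Pearson r of 0.586 and a Spearman rho of 0.375, and 62.7% had the same sign. Over all 18004 genes with reads r was 0.137 and rho 0.191, and 55% had the same sign. Genes are not independent replicates. All 7 Sult2a genes with reads rose in both sexes in the authors' edgeR test, and were counted as a family after their values were seen. Voom called Sult2a3 and Sult2a7 in females, but did not call Sult2a1, Sult2a2 and Sult2a6 in males.

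**Figure D3:**
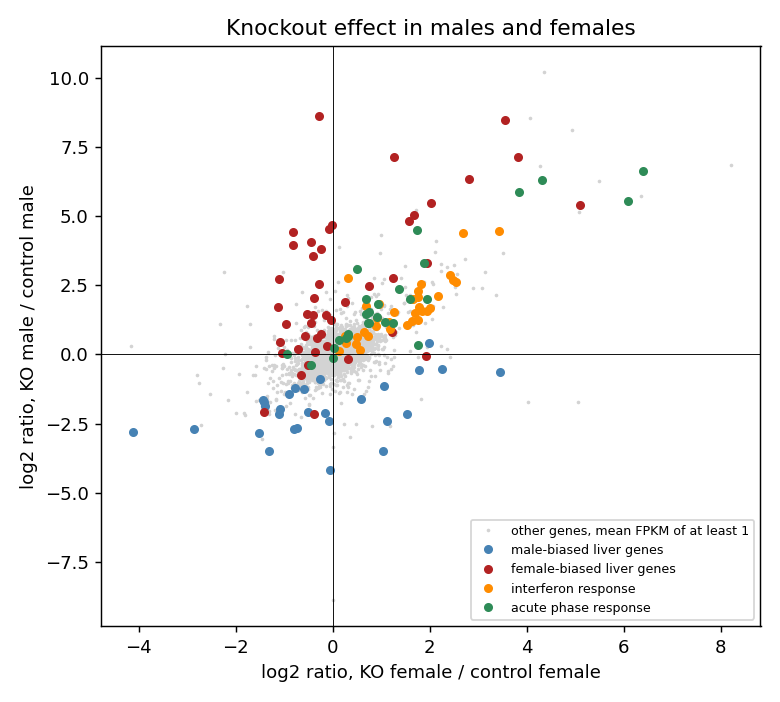
Log2 ratio of knockout to control in males (vertical axis) and in females (horizontal axis) from the authors' table, for genes with a mean FPKM of at least 1, with members of 4 lists in colour. Interferon and acute phase genes lie mostly in the upper right, with list medians of 1.47 and 1.41 in males and 1.23 and 0.831 in females, while male-biased genes have medians of -2.10 in males and -0.542 in females.

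Sex differences of control liver were taken as the baseline for both knockouts. Control females and control males share no library code, so code and sex cannot be told apart in this comparison. The authors' deposited table calls 356 genes, 166 higher in males and 190 higher in females. Within the same limits on expression and overlap, the largest male excesses, apart from the Y-linked genes Ddx3y, Eif2s3y and Uty, were Cyp4a12a (212-fold), Gm6614 (120-fold), Mup21 (55.7-fold), Mup16 (54.4-fold) and Mup20 (50.3-fold), in the authors' deposited table. Among the largest female excesses in the authors' deposited table were Sult3a1 (1520-fold), A1bg (1210-fold), Gm4794 (805-fold), Xist (431-fold), Cyp2b13 (294-fold), Sult2a2 (235-fold) and Cyp2a4 (218-fold). Cyp2b13 averaged 54.4 ± 10.5 FPKM in control females and 0.153 ± 0.0943 in control males, and Cyp4a12a 76.1 ± 14.2 FPKM in control males and 0.381 ± 0.354 in control females (SD, n = 2). Of the fixed male-biased list 29 of 34 were higher in males and 0 lower (30 adjusted over the list alone, 18 by voom; camera 1.25e-41), and of the female-biased list 38 of 46 were higher in females and 0 lower (43 adjusted over the list alone, 18 by voom; camera 4.05e-43), each with an adjusted p = 0.0578 with an estimated correlation. Sex-chromosome genes had 4 of 6 higher and 1 lower in males (camera 3.33e-06, adjusted p = 0.0578 with an estimated correlation).

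Cell type markers were compared between the control sexes as well, with the same confounding of library code and sex. Camera placed Kupffer cell markers (2.54e-06, 0 of 18 called, 11 at an unadjusted p under 0.05, 10 adjusted over the list alone), endothelial markers (4.42e-06, 0 of 17 called, 2 at an unadjusted p under 0.05) and stellate markers (3.23e-11, 2 of 23 called, Col3a1 and Lrat, 12 adjusted over the list alone) lower in control males, with adjusted p = 0.466, 0.0578 and 0.0982 with an estimated correlation. Limma voom called 0 of the Kupffer cell, 0 of the endothelial and 2 of the stellate markers. Red blood cell markers were higher in males (camera 8.89e-04, 1 of 10 called, Alas2, adjusted p = 0.537 with an estimated correlation), and immediate early genes lower (camera 0.00817, 5 of 16 lower and 2 higher, adjusted p = 0.537 with an estimated correlation), with Egr1 5.01-fold and Dusp1 3.17-fold lower in males in the authors' deposited table. The gluconeogenesis list was lower in males by camera (0.0137, 2 of 18 higher, among them G6pc, and 1 lower, Igfbp1, adjusted p = 0.466 with an estimated correlation). For control males against females limma on log2(FPKM + 1) called 64 genes (40 higher, 24 lower) and limma voom 99 (63 higher, 36 lower), and the voom count was 24 without the deeper and 50 without the shallower control female library and 65 without the shallower control male library.

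Genes with a sex difference in control liver were followed into the knockouts, using the authors' calls. Of the 166 male-biased genes 71 fell in knockout males, against 1.77 for independent lists, and 6 rose. Of the 190 female-biased genes 63 rose in knockout males, against 3.55, and 3 fell, namely Cyp2c69, Dct and Fabp5. In knockout females 36 of the male-biased genes rose, against 2.31, and 14 fell, while 26 of the female-biased genes fell, against 1.3, and 19 rose. The fixed lists, which were not chosen from these control libraries, gave the other balance in knockout females. There 5 male-biased genes rose and 9 fell, and 11 female-biased genes rose and 9 fell. These counts are small, and whether their balance differs beyond chance was not tested. The comparisons share control libraries, so chance alone gives some overlap. With voom, 26 male-biased genes fell and 7 female-biased genes rose in knockout males, and 5 male-biased genes rose and 3 female-biased genes fell in knockout females. In 20 simulations of unchanged knockouts against the same controls, voom called a mean of 0.3 genes in the male and 0.05 in the female knockout comparison, against 197 and 46 in the data, so their overlap was bound to be near 0 and does not show how much the shared controls give. The controls are too few to be split, and part of the excess may come from the shared controls.

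Knockout males and females still differed in 245 genes in the authors' deposited table, 129 higher in males and 116 higher in females; these groups share no library code either. Of the 166 genes higher in control males 62 were also higher in knockout males and 0 lower, and of the 190 higher in control females 57 were also higher in knockout females and 0 lower. Within the same limits, and apart from Eif2s3y, Ddx3y and Uty, the largest male excesses in the authors' deposited table were Adh6-ps1 (18.6-fold) and Mup21 (11.3-fold), and the largest female excesses Xist, A1bg (170-fold), Gm4794 (148-fold), Sult3a1 (75.5-fold) and Cyp2c69 (44-fold). A1bg averaged 96.5 ± 37.7 FPKM in knockout females and 0.556 ± 0.028 in knockout males (SD, n = 2). Of the male-biased list 16 of 34 were higher in males and 0 lower (21 adjusted over the list alone, 6 by voom; camera 8.79e-20), and of the female-biased list 27 of 46 were higher in females and 3 in males (32 and 5 adjusted over the list alone, 16 and 0 by voom; camera 5.67e-30), each with an adjusted p = 0.101 with an estimated correlation. The 3 were Cyp7a1, Sult1e1 and Cd36, which the authors' deposited table gives as 2.42-fold, 3.08-fold and 1.84-fold higher in knockout males.

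Other lists were also compared between the knockout sexes. Red blood cell markers had 8 of 10 higher in males in the authors' edgeR test (camera 4.38e-08, adjusted p = 0.327 with an estimated correlation; voom called 0), with the haem synthesis gene Alas2 2.21-fold higher in the authors' deposited table. These 8 hold 3 pairs of globin genes with the same reads in every library, so 5 are separate measurements, and the camera tests of this list count each pair as 2 members. Of the pancreas markers 1 was called higher in males, Ctrb1, and 4 adjusted over the list alone. PPARalpha targets had 4 of 30 lower in males, Acot3, Cyp4a10, Cyp4a14 and Vnn1 (8 adjusted over the list alone; camera 1.69e-04, adjusted p = 0.48 with an estimated correlation). Cholesterol synthesis had 0 of 23 called and 8 at an unadjusted p under 0.05 (voom called 0; camera lower with 4.39e-08, adjusted p = 0.352 with an estimated correlation), and acute phase genes had 1 of 28 higher, Orm2 (8 higher and 1 lower adjusted over the list alone; camera 2.73e-04, adjusted p = 0.448 with an estimated correlation). Camera also placed sex-chromosome genes higher in males (5.41e-07, adjusted p = 0.086 with an estimated correlation) and endothelial (6.65e-06), stellate (9.92e-05), immediate early (0.00103), gluconeogenesis (0.0038) and periportal genes (0.0292) lower, with adjusted p = 0.086, 0.327, 0.448, 0.352 and 0.602 with an estimated correlation. Limma on log2(FPKM + 1) called 16 genes (8 each way) and limma voom 50 (25 each way), and the voom count was 30 without the deeper knockout female library and 33 without either control female library.

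The last comparison tested whether the knockout effect differed between the sexes. Cyp2b13 did, by 6.14 on the scale of log2(FPKM + 1), with an adjusted p of 0.048 in limma, since it rose in males and averaged 54.4 ± 10.5 FPKM in control and 49.3 ± 5.47 in knockout females (SD, n = 2). Mir491 was the other gene past the threshold, by 0.465 with an adjusted p of 0.04, but lay near the floor, and is named here after its values were seen. Limma on log2(FPKM + 1) thus called 2 of 18004 genes, with 986 at an unadjusted p under 0.05. Limma voom called 0 of 12980, with 662 at an unadjusted p under 0.05 and a smallest adjusted p of 0.218. Both unadjusted counts lay near the number that chance alone gives. Limma-trend called 1, Cyp2b13, with an adjusted p of 0.000677. Leaving out 1 library raised the limma count each time, to 4 without the deeper and 25 without the shallower control female library, 28 and 13 for the control males, 28 and 41 for the knockout females, and 36 and 39 for the knockout males.

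By camera on the voom values, the sex-biased lists had the smallest adjusted p-values. The male-biased list was lower in males relative to females with a median log2 difference of -1.86 and 13 of 34 members adjusted over the list alone (camera 1.87e-20, adjusted p = 0.305 with an estimated correlation), and the female-biased list higher with a median of 1.51 and 20 of 46 members (camera 1.37e-21, adjusted p = 0.365 with an estimated correlation). Over all genes 0 members of either list were called by voom, with 17 and 29 at an unadjusted p under 0.05. The other lists that passed camera were acute phase (4.63e-06), Kupffer cell (1.2e-06), stellate (1.05e-04), bile duct (0.0222) and cell cycle genes (0.0377), higher in males relative to females, with adjusted p = 0.583, 0.583, 0.52, 0.448 and 0.796 with an estimated correlation. PPARalpha targets (0.0016) and cholesterol synthesis genes (0.00285) were lower, each with an adjusted p = 0.76 with an estimated correlation. The interferon list gave 0.352 in camera, which does not show that the sexes respond alike.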

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

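The tests of paralogs and of library depth, and the voom values, were chosen after the results were seen, while the interaction itself was planned. A difference of the knockout effect between the sexes, tested as an interaction, singled out the following results. Cyp2b13 differed by 6.14 in limma on log2(FPKM + 1), and Mir491 by 0.465, the latter with reads only in knockout males and near the floor.

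Adjusted over the list alone on the voom values, 13 male-biased genes were lower in males relative to females, with 0 called over all genes by voom. Of the 12980 genes that voom tested, 662 had an unadjusted p under 0.05, near the number that chance alone gives. The 13 were Cyp2d9, Cyp4a12a, Cyp7b1, Mup7, Mup20, Selenbp2, Ugt2b1, Nox4, Gstp1, C4a, C6, Bcl6 and Capn8. In the same test 20 female-biased genes were higher, among them Cyp2b9, Cyp2b13, Cyp2a4, Cyp7a1, Sult2a2 and Cd36.

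Reads divided between related gene copies are argued against as the cause of these sex-biased list results by members outside multigene families such as Cyp, Mup and Sult, which were set by symbol. The 12 male-biased ones had a median difference of -1.65 with quartiles of -2.8 and -0.606, all 12 in the same direction. The 12 female-biased ones had a median of 1.23 with quartiles of 0.496 and 1.82, 11 of them in the same direction. The choice by symbol leaves in some genes with a close copy, such as Hamp2. The difference did not rest on the shallower control male library alone. Without that library the median absolute difference over 79 members was 1.54 against 1.70 with it, with 75 in the same direction. Noise keeps an absolute difference from vanishing and the fits share all other libraries, so this is a weak test of depth. The library code stays open, since knockout females share theirs with no other group, and so does the biological explanation that STAT5 acts differently in the sexes, which the design names and no separate test addressed.

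Single members of other lists also differed in this test adjusted over the list alone. In the growth-arrest list it was 1 gene, Nox4, by -2.67. The acute phase list had 2, Serpina3n by 0.86 and Il1r1 by -1.40. Kupffer cell and macrophage markers had 1, Lyz2, by 0.91. Stellate markers had 1, Col3a1, by 1.20. The bile duct list had 1, Spp1, by 3.09. Pancreas markers had 1, Cela1, by -1.03, in a list with 1 tested member. Periportal genes had 1, Hsd17b13, by 1.15.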

How the results depend on the processing

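Limma voom and limma-trend on recovered reads, the filter at a mean FPKM of 0.5 and the correlation over all genes with reads were chosen after seeing the data, the other settings before, though some of these are applied to voom. The calls of the authors' edgeR test fell by more than a factor of 1.5 in every refit of the recovered libraries, for male knockout, female knockout, control sex and knockout sex in that order. Limma on log2(FPKM + 1) called 55, 6, 64 and 16 genes, with a pseudocount of 0.1 it called 90, 24, 80 and 23, limma voom 197, 46, 99 and 50, and limma-trend 236, 35, 174 and 24; the cause was not tested. A fold of at least 2 or adjustment over genes with a mean FPKM of at least 0.5 kept the counts within that factor (454, 250, 299 and 193; 494, 400, 338 and 210). Within voom, only the 4 libraries compared gave 103 in place of 197 and 22 in place of 50, but 69 in place of 46 for the female knockout and 142 in place of 99 for control sex, and the cause was not tested; library totals, no filter and a filter at 1 CPM stayed within that factor. Of 58 named gene calls, 26 stayed past the threshold in limma on log2(FPKM + 1) and 32 in voom, and 0 reversed. The log2 ratio of mean FPKM lay above the authors' normalized ratio by a median of 0.137 in females and 0.145 in the control sex comparison; 0 called genes changed direction between these scales.

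The interaction count of 2 became 9 with a pseudocount of 0.1, 5 with median-of-ratios scaling, 0 with voom (662 at an unadjusted p under 0.05), 1 with limma-trend and 1 with a fold of at least 2; the cause was not tested. With 1 library left out, a group's lone library is assumed to vary like the others. Voom counts then ran from 53 (deeper control male) to 285 (shallower knockout male) for the male knockout, 8 (deeper control female) to 65 for the female, and 30 (deeper knockout female) to 57 for knockout sex. For control sex, 15 (deeper control female) to 78 (either knockout male) genes were higher and 9 to 59 lower without the same libraries, against 63 and 36, with 26 higher without the shallower control female and 21 lower without the shallower control male. The interaction count ran from 4 (deeper control female) to 41 (shallower knockout female), over 1.5 times the full count in each case. Lists passing camera ran from 9 to 13, 7 to 14, 6 to 13, 12 to 16 and, for the interaction, 5 (deeper control male) to 14 (shallower knockout male), against 11, 10, 9, 12 and 9 with all libraries. With an estimated correlation 0 lists passed in all 5 comparisons, and with fry 2, 1, 6, 4 and 0.

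With the fixed lists in place of genes called in control livers, fewer genes enter, which lowers the counts. Then 29 male-biased genes fell in knockout males against 71, and 28 female-biased genes rose against 63. In knockout females 5 and 9 male-biased genes rose and fell against 36 and 14, and 11 and 9 female-biased genes against 19 and 26. The balance of calls thus turned for both lists in knockout females, but on few genes. Whether the turn exceeds chance was not tested, nor was its cause. By voom 2 male-biased list genes rose and 0 fell there, and 4 female-biased list genes rose and 3 fell. The correlation of male and female effects was 0.612 at an average log2 CPM of at least 3 and 0.137 over all genes with reads, against 0.586; the cause was not tested. No paired analysis was possible because the recovered libraries carry no pool number. DESeq2, size factors (RLE) in edgeR, the replicate block and the library code as a covariate were not run. The shallower control male library had the fewest reads in genes, 2288033.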

Other observations

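All tests of explanations in this part were chosen after the results were seen. Genes of MHC class II antigen presentation, a list chosen after the data were seen, were higher in both knockouts, 4 of 6 in males and 5 of 6 in females in the authors' edgeR test. The authors' deposited table gives Cd74, the invariant chain, as 9.55-fold higher in males with an adjusted p of 9.2e-10 and 4.71-fold in females with 1.7e-06, and H2-Ab1 as 4.38-fold and 3.02-fold higher. Cd74 averaged 12.1 ± 2.78 FPKM in control and 115 ± 82.2 in knockout males, and 19.1 ± 2.6 in control and 98.9 ± 68.5 in knockout females (SD, n = 2). The knockout libraries of a sex differed widely, and the voom adjusted p of Cd74 was 0.063 in males and 0.24 in females. Around the deleted locus, and apart from Stat5a and Stat5b themselves, 60 genes with a mean FPKM of at least 0.5 lay within 2 Mb of Stat5a, of which 1 was called in males, Adam11, and 2 in females, Adam11 and Dhx58, all of them higher. Adam11 averaged 1.23 ± 0.27 FPKM in control and 6.22 ± 1.64 in knockout males (SD, n = 2).

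The rise of class II genes in both sexes was weighed against 2 technical explanations. For B cells and dendritic cells brought in with the tissue, the summed FPKM of their markers gained 0.193 FPKM in males and -0.27 in females. These were 0.141% and -0.208% of the class II gains of 136 and 130 FPKM. The most abundant of these markers, Cd79b, Ms4a1 and Cd79a, are B cell genes, each higher in knockout males and lower in knockout females than in controls. What a marker and a class II gene yield per cell is not known here, so the sums do not exclude these cells, least of all dendritic cells. A strain variant at the MHC on chromosome 17, carried along with the floxed or Cre alleles, stays open. Cd74, on chromosome 18, had a log2 ratio of at least 2.24 in both sexes, but it is 1 gene of a list chosen because its members rose, and voom did not call it. Macrophages or hepatocytes with more class II expression may be the source, as may added dendritic cells, and the data do not separate them.

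Interferon and acute phase genes were higher in both knockout sexes. Extra macrophages that carry the listed markers evenly are argued against as the whole cause. In males the macrophage list had a median log2 ratio of 0.533 and an upper quartile of 0.718, below the interferon list's lower quartile of 0.875. In females the median was 0.15 and the upper quartile 0.227, below 0.59. Mpeg1, the most abundant of these markers, rose from 6.24 to 38 FPKM in males and from 5.61 to 25.4 in females. Clec4f changed less, from 8.54 to 13.2 and from 11.6 to 12.7, as did Cd5l, from 8.83 to 11.9 and from 11.2 to 14.3. The list mixes Kupffer cell and general macrophage genes, so macrophages with part of the markers are not excluded. The medians of the lymphocyte and neutrophil lists in males, 1.14 and 1.66, lay near the interferon median of 1.47 and do not argue against these cells. Lymphocyte and neutrophil markers gained 0.844% of the summed FPKM that the interferon genes gained in males and 0.0231% in females. These gains were 1.93 and 0.0714 FPKM against 228 and 309 FPKM. What each gene yields per cell is not known here, so these small shares do not exclude such cells. Among lymphocyte markers, Cd3e went from 0.436 FPKM in control to 0.879 in knockout males and from 1.22 to 1.2 in females. Gzmb went from 0.0242 to 0.206 in males and from 0.0979 to 0.379 in females, and Cd4 from 0.249 to 0.264 and from 0.077 to 0.132. The most abundant neutrophil markers stayed low in males, with Cxcr2 at 0.952 FPKM in control and 1.04 in knockout, S100a8 at 0.412 and 0.596 and S100a9 at 0.626 and 0.375, and in females they went from 0.925 to 0.916, 1.01 to 0.409 and 0.764 to 0.855. In males, where 1 knockout library shares its code with the controls, the lowest knockout library exceeded the highest control library by a median log2 of 0.644 over 46 interferon genes with a lower quartile of 0.289 and 42 above 0, which argues against the code. In females that median was 0.447 with 39 above 0, but the groups share no code, so code and genotype cannot be told apart. A response of hepatocytes to the loss of STAT5 may be a candidate explanation in males and stays untested, and an infection or inflammation of the knockout animals was not tested.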
